A study of Mus musculus with 4 samples.

How the data were processed

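SSRP1 binding was measured by ChIP-seq, in which DNA bound to a protein is pulled down with an antibody and sequenced. SSRP1 is a subunit of FACT, a histone chaperone that handles nucleosomes during transcription and replication. The cells were E14 mouse embryonic stem cells, an established pluripotent line kept in serum with LIF. The labels name 2 SSRP1 ChIP samples and 2 input samples, numbered 1 and 2 in each group. Per the labels' protocols, the cells were fixed with 1% formaldehyde for 10 min, chromatin was sheared by sonication, and 5 µg of SSRP1 antibody was used. Nothing in the labels says whether the 2 replicates came from separate cultures, so all p-values describe these 2 peak lists and their spread may be technical.

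The data are 2 peak lists, 1 per ChIP sample, and each was called separately, as the peak names in the files show. Processed values of the input samples were not analysed here. STAR, MACS2, deepTools and the build mm9 are listed in the submitters' processing notes, which give no roles. Their versions, settings and control samples are not given in the sources used here. Each list gives for every peak its start, end and summit on mm9, the authors' fold enrichment at the summit over the local background (a ratio), the authors' −log10 p and −log10 q, and a peak score. The deposited score was the whole part of 10 times the −log10 q in 100% of the peaks of both lists, and it was not used further. The largest q-value was 0.0471 in replicate 1's list and 0.0331 in replicate 2's list. All folds and q-values printed here are the authors' own. They describe and rank peaks within a list, and where they are set side by side between the lists they compare the lists and do not measure a change in binding. The lists give no read totals.

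Both lists were read with Python 3.11.15 and pandas 2.3.3. Peaks were called shared when they overlapped a peak of the other list by at least 1 bp. The overlap was set against 10000 placements of replicate 2's peaks at random on their own chromosome, within the span that both lists cover, with a one-sided p whose smallest value is 0.0001. Such placements ignore mappability and open chromatin. For fold comparisons each shared peak was paired with its strongest partner and each partner was used once. Medians and correlations were tested two-sided with 100000 permutations (numpy 2.4.6), whose smallest p is 1e-05. These tests run across peaks, which are not independent replicates. Shares have exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only. A binomial test of each chromosome against its length had been planned, but chromosome lengths of mm9 were not used here. Chromosomes were therefore compared between the lists by Fisher's exact test (scipy 1.17.1) with Benjamini-Hochberg adjustment over 21 chromosomes (statsmodels 0.14.6). In all Fisher tests between the lists, shared sites count on both sides, so the sides are not independent samples. Clustering was measured as the number of 1 Mb windows with 5 or more summits.

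The depth behind each peak was recovered from its fold and p-value, a step added after the files had been seen. MACS2 computes the fold as (pileup + 1) / (background + 1) and the p-value from the Poisson tail of the whole part of the pileup. Both are printed to 5 decimals, so pileup and background can be solved for. In replicate 1's list all 5011 pileups were whole numbers within 0.01. In replicate 2's list all 2342 were whole multiples of 0.416 within 0.01 of a fragment. With other step sizes at most 19.5% and 7.22% of the peaks came out whole. The lowest background, taken as the genome-wide one, was 2.28 in replicate 1's list and 2.07 in replicate 2's list. Backgrounds above 8 were whole multiples of 0.819 in 92.5% of 160 peaks of replicate 1 and of 1 in 87.2% of 78 peaks of replicate 2, within 0.02. These steps are what remains when the larger library is scaled down to the smaller. If each list was called by these formulas against 1 control library, they put the ChIP library at 0.819 times the depth of its control in replicate 1 and at 2.40 times in replicate 2. With the same fragment length in both lists, whose shortest peaks were both 200 bp, the recovered ChIP depth of replicate 2 was 2.19 times that of replicate 1, that of its control 0.746 times, and the depth after scaling 0.910 times. These are depths of the reads kept for peak calling and were not checked against read totals.

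The procedures were tested on simulated data. Of 200 shared peaks planted in lists of the real sizes, the overlap count returned 210 where chance adds 5.42. For the overlap, 3 of 40 runs without sharing had p under 0.05. For clustering, 3 of 40 runs at random positions did, and of 10 planted windows 7.74 were found beyond the random mean. Without an effect, the test of medians gave p under 0.05 in 9 of 100 runs and the correlation in 6 of 100. The recovery returned the exact fragment count for 99.95% of 2000 simulated peaks without scaling and for 100% with it.

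The tests of overlap, fold correlation, shared against unshared peaks, rank and clustering, the alternatives listed next and the rule for the peaks named in the text were fixed before the data were examined. The fold tests within windows, the comparisons of widths and of wide peaks, and those of peaks over a high background were added after the data had been seen. The rule takes the 20 shared peaks with the highest lower-of-the-two fold, the 5 windows of 1 Mb with the most shared peaks, and the 3 strongest unshared peaks of each list. The alternatives fixed in advance were −log10 q minimums of 5 and 10, a 50% overlap of both peaks, summits within 200 bp, lists of equal length, placements within 1 Mb, merging within 1 kb, autosomes only, leaving out dense windows, windows of 100 kb with 3 or more peaks, and each list alone. Alternatives added later left out peaks whose background was 3 or more times the genome background, left out single windows, used recovered fragments over the genome background, compared each window with all other pairs, or added a window that tied for the fifth place. Gene annotation, the 13 gene lists fixed in advance, genomic features and sequence composition were not analysed. The gene table used here is of the build GRCm38, not mm9: its last gene on chromosome 7 ends at 145324059, while the last peak on chromosome 7 ends at 152128719. Positions are therefore given without gene names, and the table served only to count genes per chromosome.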

Results

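The series measured SSRP1 binding across the genome in E14 mouse embryonic stem cells. It comprised 2 SSRP1 ChIP samples and 2 inputs, and 1 peak list was used for each ChIP sample. Replicate 1's list held 5011 peaks covering 2168 kb and replicate 2's list held 2342 peaks covering 1321 kb. Peaks were narrow, with a median width of 301 bp in replicate 1 and 346 bp in replicate 2, and most were modest. The median fold enrichment was 4.57 in replicate 1 (interquartile range 3.92 to 5.50) and 5.45 in replicate 2 (4.60 to 7.12). Read totals were not given. The recovered number of ChIP fragments over a summit had a median of 19 in replicate 1 (range 10 to 385) and of 44 in replicate 2 (range 26 to 400). Both lists covered the 19 autosomes, X and Y. Positions below are on mm9 and count from 1. No mm9 annotation was used, so no statement is made on whether a position is in an exon, an intron or a UTR.

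The comparison between replicates shows which sites were found in both samples. Of replicate 1's peaks, 1386 overlapped a peak of replicate 2, which is 27.7% (95% interval 26.4 to 28.9%). Of replicate 2's peaks, 1286 were shared, which is 54.9% (52.9 to 56.9%). Random placement of replicate 2's peaks gave a mean of 5.37 overlapped peaks and never more than 19, so the overlap was 258 times the random mean (one-sided permutation of peak positions, p = 0.0001, the smallest that 10000 placements can give). Summits of the 1229 shared pairs lay a median of 56 bp apart. With peaks moved by up to 1 Mb only, the random mean was 19.3, and the observed overlap again exceeded every placement (permutation p = 0.0001).

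Strong peaks were shared far more often than weak ones. In replicate 2's list all 100 peaks with the highest −log10 q were also found in replicate 1 (95% interval 96.4 to 100%), and 94 of replicate 1's top 100 were found in replicate 2 (87.4 to 97.8%). With each list ranked by −log10 q and split into 4 equal parts, the shared fraction in replicate 1 was 59.3%, 24.7%, 15.5% and 11.2% from the strongest to the weakest part. In replicate 2 it was 85.8%, 53.9%, 46.5% and 33.4%. The median fold was 5.38 for shared and 4.38 for unshared peaks in replicate 1, and 6.26 against 4.93 in replicate 2 (permutation p = 1e-05 in each list, the smallest possible). Shared peaks were also wider, with medians of 408.5 against 275 bp in replicate 1 and 429 against 285 bp in replicate 2.

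**Figure D1:**
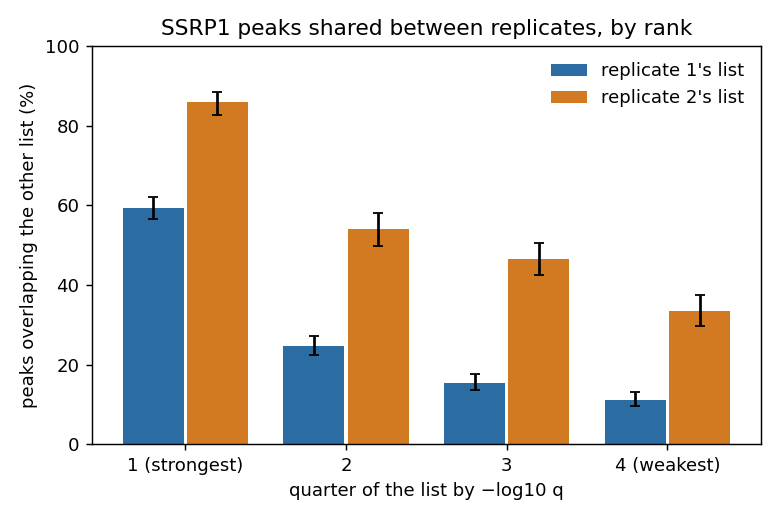
Share of peaks (%) that overlap a peak of the other list, in 4 equal parts of each list ranked by −log10 q, with exact 95% binomial intervals as error bars. The share falls from 59.3% to 11.2% in replicate 1's list and from 85.8% to 33.4% in replicate 2's list.

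The 20 strongest shared peaks lay on 12 chromosomes. Their fold enrichment ranged from 21.05 to 104 in replicate 1 and from 20.03 to 54.0 in replicate 2. Most were short, with median widths of 480 bp and 505.5 bp, and their summits were a median of 14.5 bp apart. The strongest was on chromosome 7 at 10910676 to 10911301, with a fold of 104 in replicate 1 and 54.0 in replicate 2. The second was on chromosome 9 at 4138779 to 4139327, with folds of 81.5 and 48.5. The third, on chromosome 6 at 68749185 to 68749679, had folds of 85.6 and 48.4. The fourth, on chromosome 3 at 112893742 to 112894437, had folds of 72.0 and 47.2. On chromosome 12, the peak at 25109845 to 25110269 was about as strong in both samples, with folds of 49.1 and 45.8. A wider peak of chromosome 18, at 24829661 to 24832106, had folds of 70.6 and 45.0. Chromosome 17 held a peak at 21938369 to 21938828 with folds of 72.9 and 44.9. On chromosome 2, the peak at 98170105 to 98170594 had folds of 64.1 and 44.2, and the peak at 23146557 to 23146995 had folds of 39.3 and 36.8. The tenth, on chromosome 7 at 27274511 to 27274980, had folds of 43.7 and 34.9. The other 10 had a lower-of-the-two fold between 20.03 and 34.8.

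Of these 20 peaks, 16 had the higher fold in replicate 1 and 4 in replicate 2. Over all 1229 shared pairs 785 (63.9%) had the higher fold in replicate 2, with a median ratio of 1.17. This direction depended on the scale: with recovered fragments over the genome background 495 pairs (40.3%) were higher in replicate 2, with a median ratio of 0.915, and 2 of the 20 strongest were. The background at the summit was under 2 times the genome background in 17 of the 20 peaks in replicate 1 and in all 20 in replicate 2. At the strongest peak the recovered counts were 359 ChIP fragments in replicate 1 and 396 in replicate 2, and no peak of either list had more than 400. These 359 and 396 fragments gave folds of 104 and 54.0, as each fragment of replicate 2 counted as 0.416. If 400 was a limit, replicate 2's fold could hardly exceed 54.0, and the 16 of 20 may partly follow from that. Across shared pairs the folds of the replicates correlated, with Spearman's rho = 0.49 and Pearson's r = 0.61 on the log2 scale (permutation p = 1e-05 for each, the smallest possible). This correlation is across peaks of 2 libraries.

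**Figure D2:**
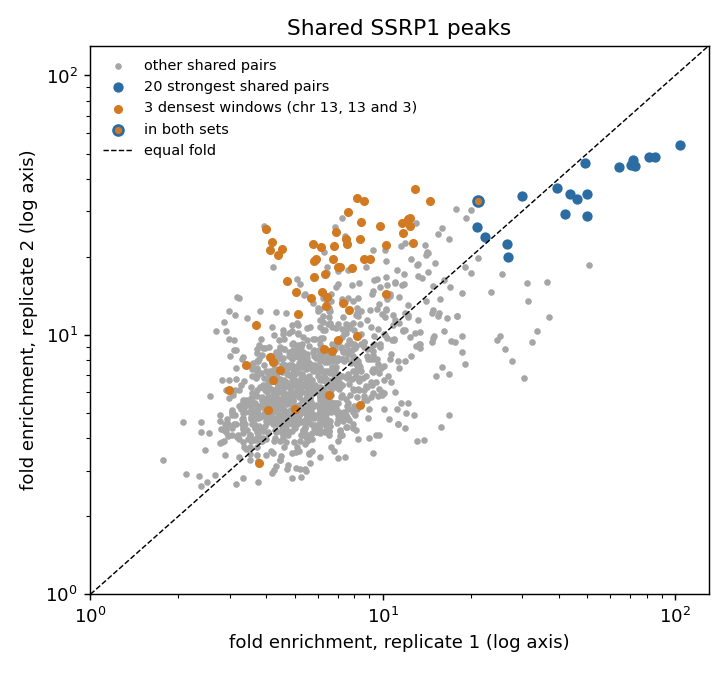
Fold enrichment of 1229 shared pairs in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, where each point is a pair and the dashed line marks equal fold. Most of the 20 strongest pairs lie below the line (16 of 20), whereas nearly all pairs in the 3 windows with the most shared peaks lie above it.

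Peaks were gathered in dense regions. Shared peaks filled 74 windows of 1 Mb with 5 or more peaks each, against a mean of 3.95 and a highest value of 13 in random placements (one-sided permutation of positions, p = 0.0001, the smallest possible). These windows held 46.9% of the shared peaks. After merging peaks within 1 kb, 36 such windows were left (random mean 1.09, permutation p = 0.0001). The counts were 327 windows for replicate 1's whole list (random mean 172) and 134 for replicate 2's (random mean 14.9), each with a permutation p = 0.0001. The densest window was on chromosome 13 between 23 and 24 Mb, with 29 shared peaks among 35 in replicate 1 and 33 in replicate 2, all of the shared ones between 23529745 and 23856149. The next was also on chromosome 13, between 21 and 22 Mb, with 21 shared peaks between 21264473 and 21926662. A window on chromosome 3 between 96 and 97 Mb held 20, from 96023885 to 96299222. A window on chromosome 8 between 44 and 45 Mb held 19, all within 44372311 to 44389978, and merging peaks within 1 kb turned these into 2 regions. A window on chromosome 10 between 79 and 80 Mb held 18, spread from 79151633 to 79896229. A window on X from 166 to 167 Mb also held 18 and tied with it for the fifth place. With −log10 q of 10 or more the 5 windows held 18, 12, 11, 7 and 4 shared peaks in the order given, and with 50% overlap 16, 13, 13, 10 and 11.

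In 3 of these windows the ratio of replicate 2's fold to replicate 1's was higher than in the other pairs, and on chromosome 13 this held on both scales of background. The sign-flip tests given per window are against equal folds, while the median ratio over all pairs was 1.17. Each fold was computed within its own list against its own local background, so these values compare the lists and do not measure a change in binding. In the 23 to 24 Mb window of chromosome 13 all 26 pairs were higher in replicate 2, with median folds of 7.02 in replicate 1 and 18.97 in replicate 2 (median log2 ratio 1.34, SD 0.56 over pairs; sign-flip permutation test, adjusted p = 2.5e-05 over 5 windows). In the 21 to 22 Mb window all 20 pairs were higher, with medians of 6.42 and 21.5 (median log2 ratio 1.55, SD 0.66; permutation test, adjusted p = 2.5e-05). In the chromosome 3 window 14 of 17 pairs were higher, with medians of 6.55 and 12.9 (permutation test, adjusted p = 0.000817). The window on chromosome 8 had medians of 6.22 and 6.65, with 11 of 14 pairs higher (exact permutation test, adjusted p = 0.02). In the chromosome 10 window 9 of 16 pairs were higher, with medians of 6.01 and 6.49 (exact permutation test, adjusted p = 0.631). Pairs in the 5 windows had a median log2 ratio of 1.02, against 0.19 for the 1136 other pairs (permutation p = 1e-05, the smallest possible). With the tied window on X, whose own median was −0.04 with 7 of 16 pairs higher in replicate 2, the values were 0.75 and 0.20 (permutation p = 1e-05). Over the genome background the median ratios were 2.17 and 1.85 in the 2 windows of chromosome 13, 1.04 on chromosome 3, 1.50 on chromosome 8, 0.782 on chromosome 10 and 0.863 on X. Against all other pairs, the log2 ratio was higher by 1.13 and 1.34 in the windows of chromosome 13 and by 0.90 on chromosome 3 (permutation test, adjusted p = 2e-05 for each over 6 windows), but by 0.03 on chromosome 8 (permutation test, adjusted p = 0.892). Over the genome background these differences were 1.28, 1.04, 0.19 and 0.73 (permutation test, adjusted p = 3e-05, 3e-05, 0.276 and 0.00014), so that chromosomes 3 and 8 passed on 1 scale each. The windows on chromosome 10 and X passed on neither (permutation test, adjusted p from 0.184 to 0.594). Peaks of 1 window are neighbours and not independent.

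**Figure D3:**
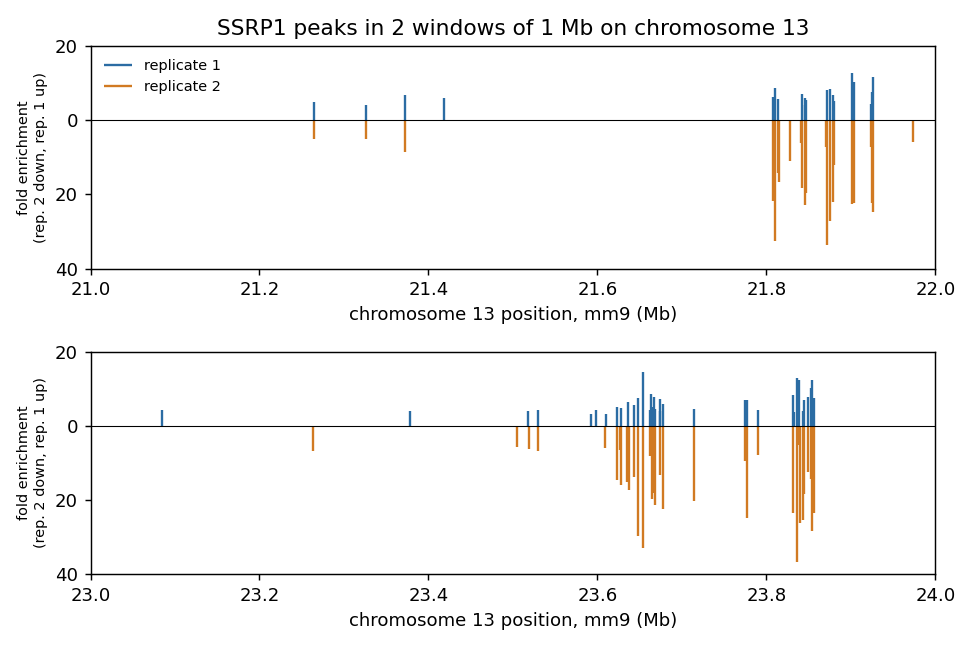
Peaks in 2 windows of chromosome 13 (x axis, position in Mb on mm9), drawn as lines whose height is the fold enrichment, upwards for replicate 1 and downwards for replicate 2. Of replicate 1's peaks, 29 of 35 in the window from 23 Mb and 21 of 22 in that from 21 Mb overlap a peak of replicate 2, and the shared pairs have median folds of 6.42 and 21.5 between 21 and 22 Mb and of 7.02 and 18.97 between 23 and 24 Mb.

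The chromosomes were not covered evenly. Chromosome 11 held the most peaks in both lists, with 410 in replicate 1 and 217 in replicate 2, while X held 74 and 63. Per Mb of the spanned length this was 3.48 and 1.84 peaks on chromosome 11, 3.29 and 1.64 on chromosome 17, and 0.462 and 0.394 on X. Both lists also held peaks on Y (21 and 19). The number of X copies in these cells was not taken into account, so the low density of X may reflect it. Between the lists, 3 of 21 chromosomes differed in their share after adjustment (Fisher's exact test, two-sided). Chromosome 13 took 4.35% of replicate 1's list and 6.15% of replicate 2's (Fisher's exact test, adjusted p = 0.00819). X took 1.48% and 2.69% (Fisher's exact test, adjusted p = 0.00819). Chromosome 4 took 7.76% and 5.68% (Fisher's exact test, adjusted p = 0.00819). The shared fraction of replicate 1's peaks was 47.7% on chromosome 13 and 62.2% on X, against 22.1% on chromosome 4. Without the 2 densest windows the odds ratio of chromosome 13 fell from 1.44 to 1.16 (Fisher's exact p = 0.265). For X against the autosomes it was 1.85 (exact p = 0.000553), and 1.50 without the window from 166 to 167 Mb (exact p = 0.0568), 1.41 with −log10 q of 5 or more (exact p = 0.0896), 1.299 with 10 or more (exact p = 0.256) and 1.52 after merging (exact p = 0.0714). For chromosome 4 the odds ratio was 0.715. With −log10 q of 10 or more it was 0.676, no smaller a difference, but significance was lost with the fewer peaks (exact p = 0.0846). After merging it was 0.836 (exact p = 0.137).

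**Figure D4:**
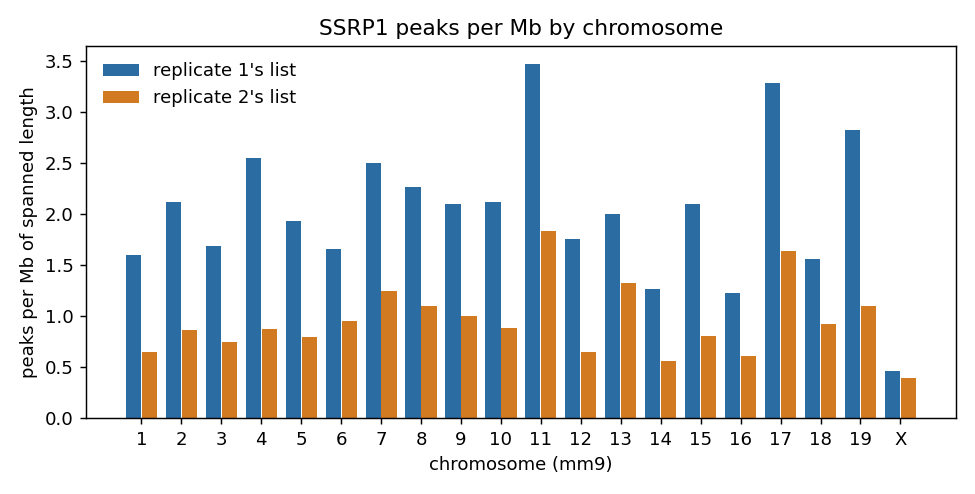
Peaks per Mb (y axis) on each autosome and X (x axis), over the length that both lists span on mm9, for replicate 1's and replicate 2's list. Chromosome 11 is highest in both lists with 3.48 and 1.84 peaks per Mb, and X is lowest with 0.462 and 0.394.

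Some strong peaks were found in 1 sample only. The strongest peak of replicate 1 without a partner was on chromosome 12 at 86814803 to 86820031. It was 5229 bp wide with a fold of 34.0, and the nearest peak of replicate 2 was 590 kb away. The next were on chromosome 7 at 19891579 to 19895308 (3730 bp, fold 23.5) and on chromosome 3 at 145308910 to 145313001 (4092 bp, fold 21.7). In replicate 2 the strongest unshared peaks were weaker and narrower. They were on chromosome 13 at 23634448 to 23635186 with a fold of 15.1, on chromosome 13 at 21813328 to 21813635 with a fold of 14.1, and on chromosome 18 at 81991913 to 81992327 with a fold of 12.5. The 2 on chromosome 13 lay 1.19 kb and 0.565 kb from a peak of replicate 1, inside the densest windows.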

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

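Leaving out peaks of high background or single windows, the scale of recovered fragments, the medians of fold ratios and the added window on X were chosen after the data had been seen. Of 147 recomputed values 82 kept their direction, side of the threshold or size, 54 moved in size, 8 lost significance, 1 gained it and 2 reversed. Some of these outcomes were fixed in advance, so the tally is no measure of robustness. Placements within 1 Mb leave the observed overlap unchanged, and a stricter minimum can only shorten a list. Both reversals came with fragments over the genome background. The median log2 ratio of replicate 2 over replicate 1 went from 0.23 to −0.13 over all pairs. It went from 0.02 to −0.35 in the window on chromosome 10. Both scales use the same recovered counts, so the reversals come from the background divided by and from the 1 that the fold adds. In that window the pairs' median background was 3.36 in replicate 1 (genome 2.28) and 2.07 in replicate 2 (genome 2.07). Of all peaks, 596 of 5011 in replicate 1 and 1149 of 2342 in replicate 2 lay at the genome background. The overlap, the clustering, the correlation of folds and the higher fold of shared peaks stayed past their tests' thresholds in the alternatives run for each. For the correlation and the shared against unshared folds these did not include merging, autosomes, dense windows left out or high background, and for clustering not the overlap rules, equal lengths or autosomes. A −log10 q minimum of 5 left 2677 and 1475 peaks in the lists, 868 shared (32.4% of replicate 1's list), and 38, 143 and 69 dense windows among shared peaks, replicate 1 and replicate 2. A minimum of 10 left 989 and 717 peaks, 443 shared (44.8% and 59.97% of the lists), and 14, 40 and 24 windows. Requiring 50% overlap gave 853 shared peaks (17.02% and 36.4%). Summits within 200 bp gave 20.2% and 43.2%, equal list lengths 43.5% and 43.04%, and merging within 1 kb 26.4% and 59.0%. Without windows of 5 or more peaks 311 were shared (18.1% and 43.5%), and without peaks of high background 26.0% and 51.9% were. Merging left 36 dense windows of shared peaks and 65 of replicate 2. Windows of 100 kb gave 129 and 232. Each list alone gave 134 to 327 windows in place of the 74, and an X share of 1.48 to 2.69% in place of 3.32%. These are the lists' own values given above. A whole list holds more peaks than its shared part, so its higher number of windows is no check on the 74. The X share of shared peaks was 4.84% and 7.22% with the minimums of 5 and 10 and 2.08% without peaks of high background. The odds ratio of X between the lists lost significance with the minimums (1.41 and 1.299), after merging (1.52) and without the window at the end of X (1.50). The stricter minimums compare fewer peaks and merging makes fewer, wider regions; beyond that the cause was not tested. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, had no values here. Leaving out a replicate gives no overlap, correlation or comparison between lists. Genomic features, gene lists and sequence composition were not run, since the gene table is of another build. Precision is limited by 2 lists and by 10 to 26 fragments at the weakest summits.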

Other observations

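The tests on the ChIP depth, the single factor, the ceiling, the local input, the wide peaks' number, threshold and background, the peaks over a high background and the histone genes were chosen after the result was seen. For the tests on thinning, weak peaks and gene number the outcome was not known beforehand, but the patterns that prompted them were. The labels separate the replicates by number alone, so no biological explanation of a difference between them was tested.

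Replicate 1's list held 40 peaks of 3 kb or more, of which 12 had no partner in replicate 2. Replicate 2's list held 31, of which 1 had none (odds ratio 12.9, Fisher's exact p = 0.00443 over peaks). Narrower peaks were also more often unshared in replicate 1, at 72.7% against 45.7% in replicate 2 (odds ratio 3.17). The lists differed in length mostly among weak peaks, with 357 against 326 peaks at −log10 q of 20 or more. The 12 wide unshared peaks had −log10 q of 16.3 to 167.8, so the rate of the narrower peaks may not carry over to them. Whether the 2 odds ratios differ was not tested. Among the 10 strongest unshared peaks 5 were this wide in replicate 1 and 0 in replicate 2. Besides the 3 named above they were on chromosome 3 at 96361821 to 96366539 with a fold of 18.5, and on chromosome 10 at 24315413 to 24319610 with a fold of 18.4. Some lay side by side: on chromosome 7 a wide unshared peak at 19887016 to 19891342, with a fold of 9.03, ended just before the one at 19891579.

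These 12 wide peaks had folds of 7.79 to 34.0 in replicate 1, with a median of 10.9. Values just under replicate 2's threshold stay open: the lowest fold listed there at genome background was 3.85, and lowering each fold by the lowest ratio of the 25 wide shared pairs (0.385) left 9 of 12 above it. The 5th percentile of all shared pairs (0.584) left 12, but shared pairs are chosen for passing both thresholds, so neither ratio bounds what unshared peaks may have. Input-rich regions stay open too: in replicate 1 the median background of the 12 was 1.38 times the genome background, but replicate 2's background was recovered at 0 of the 12. A difference between the 2 samples in culture or handling stays open and was not tested.

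Replicate 2's list was the shorter one, with 2342 against 5011 peaks, yet its recovered ChIP depth was the higher one. A shallower ChIP library is argued against by this depth, 2.19 times that of replicate 1, as far as the formulas and an equal fragment length hold and for the reads kept for peak calling. A lower depth after scaling to the input was examined by thinning replicate 1's fragments to 0.910. This left 4775 peaks (SD 11.6 over 100 draws) past replicate 2's lowest −log10 p of 4.70. Before thinning, 4939 of replicate 1's 5011 peaks passed that value. Losing that share of fragments is argued against as the whole cause, for peaks already in replicate 1's list. The draws removed whole fragments, whereas each fragment of replicate 2 counted as 0.416 and each of replicate 1 as 1. Whether such scaling of counts itself shortened replicate 2's list therefore cannot be told from the thinning and stays open. The lists differed in length mainly among weak peaks near the threshold. The ratio of list lengths fell from 2.14 over all peaks to 1.38 at −log10 q of 10 or more and to 0.875 at 50 or more. This fall describes where the lists differ. Other causes of a shorter list could give it too, so it favours none. Why replicate 2 lists fewer weak peaks was not tested.

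The ratio of replicate 2's fold to replicate 1's had a median of 0.713 in the 20 strongest shared peaks, 2.02 in the 5 densest windows and 1.15 in the other 1117 pairs, and over the genome background 0.627, 1.56 and 0.890, so that the other pairs changed direction. One factor between the libraries is argued against by the difference of 0.81 (log2) between the densest windows and the other pairs (permutation p = 1e-05, the smallest possible). Over the genome background the difference was also 0.81 (permutation p = 1e-05), but the windows were unlike. Local input is argued against for the 2 windows of chromosome 13, which still exceeded all other pairs by 1.28 and 1.04 (permutation test, adjusted p = 3e-05 for each). It is not for chromosomes 3 and 10, with differences of 0.19 and −0.23 (permutation test, adjusted p = 0.276 and 0.227). On chromosome 3 the median ratio fell from 2.18 to 1.04. The window on chromosome 8 had a difference of 0.73 on this scale but 0.03 over the local background. For part of the strongest peaks a ceiling is a candidate explanation. Among 7353 recovered counts the highest was 400, which is 2 strands times the shortest peak width of 200 bp. Such a limit would arise if 1 read per position and strand had been kept. In the 11 of the 20 peaks that the depth ratio puts above 400, replicate 2 held 265 to 396 fragments. This was a median of 1.31 times replicate 1's count (range 1.103 to 1.85). Keeping 1 read per position and strand can lower counts below 400 too, so a count under 400 does not show that a peak was unaffected. The 11 were picked by replicate 1's count and no count passed 400, so their ratio had to fall below 2.19 whatever the cause. Their low ratio, and its contrast with the other 9 peaks, is therefore no evidence for a ceiling. In the other 9 peaks this ratio was 2.10 (range 1.20 to 2.79), with at most 336 fragments in replicate 2. Whether such a limit lowered these counts was not tested. The low ratios among the 9 and the high ones of the densest windows stay open.

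A hypothesis is that peaks follow the number of genes. Across 19 autosomes and X, shared peaks per Mb correlated with protein-coding genes per Mb (Spearman's rho = 0.80, permutation p = 4e-05, adjusted p = 6e-05 over 3 relations; Pearson's r = 0.71, p = 0.00098, adjusted p = 0.00098). Without chromosomes 7 and 11, those farthest from the median gene density, r was 0.62 (permutation p = 0.0078). Replicate 1's list gave rho = 0.86 (permutation p = 2e-05, adjusted p = 6e-05) and r = 0.82 (p = 1e-05, adjusted p = 3e-05), with r = 0.81 without those chromosomes. Replicate 2's gave rho = 0.72 (permutation p = 0.00043, adjusted p = 0.00043) and r = 0.78 (p = 7e-05, adjusted p = 0.000105), with r = 0.68. Genes were counted on another build, per chromosome only, and chromosomes differ in more than gene number. X was included without regard to its number of copies.

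A second hypothesis is that the densest windows hold replication-dependent histone genes, which lie in clusters in the mouse. The gene table puts 55 of 70 histone genes on chromosome 13 and 10 on chromosome 3. The number of the 3 densest windows on the 2 chromosomes with the most histone genes was 3, while 6 of the 74 dense windows lie on them (exact hypergeometric p = 0.000309, computed on the windows that prompted the idea and so no independent evidence). Whether replication-dependent histone genes in these windows account for the density cannot be told from these tables, because no gene position was compared with a peak on mm9.

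Peaks over a background of 3 or more times the genome background were few, 209 in replicate 1 and 113 in replicate 2, and 22 and 20 of them were on X. In replicate 1, 61.2% of them were shared, against 26.2% of the rest (Fisher's exact p = 4.06e-25 over peaks). In replicate 2 the shares were 59.3% and 54.7% (exact p = 0.383). On X they gathered in the last window, where 18 shared peaks lay between 166407736 and 166440882, and where the 16 pairs had a median background of 14.3 in replicate 1 and 11 in replicate 2.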
